A study of Mus musculus with 8 samples.

How the data were processed

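RNA from sorted CD8 T cells of 4 aged mice was hybridised to 8 Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample. Per the labels' protocols, RNA was isolated from frozen cells for all samples in parallel, amplified in a double procedure and labelled with biotin. The deposited table holds a linear intensity for each of 45101 probe sets, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. In the deposited values each array has a 2% trimmed mean of 500, so no further scaling was applied. The table carries no detection calls. Double amplification favours the 3' ends of transcripts, and scaling to a common trimmed mean hides any change in total RNA per cell. Records of the scanner software were read only to look for batches. They separate the array of expansion 4 from the rest, so that record and that sample cannot be told apart.

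Values were taken as log2(value + 5), the pseudocount being the 10th percentile of all values rounded to a whole number, so fold changes are on that scale and understate changes of dim probe sets. The 64 control probe sets and probe sets whose mean log2 value was not above the median were left out, which kept 22518 probe sets above a signal of about 45.3. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with mouse as a fixed block because the study design pairs the samples of each animal. Deviations from the group means correlated between the samples of the same mouse at 0.374, 0.0771, 0.214 and 0.338. The partner was not always the closest match. Expansion 2 correlated more with polyclonal sample 4 (0.131), and expansion 3 more with polyclonal sample 2 (0.301). The first model had 1 coefficient for all expansions, leaving 3 residual degrees of freedom. In the second, the alpha4-low and alpha4-high expansions had their own coefficients, leaving 2. Its alpha4-low coefficient and the difference between its coefficients were tested. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05.

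As a level of background, the 95th percentile of 27 probe sets for bacterial genes that had evidently not been spiked in was taken on each array, after the data had been examined. It was between 33.7 and 61.9. Where a gene was not above it on any array of a group, the fold is given as a bound against that level, as the mean log2 signal of the brighter group against the mean of the higher of the background level and the signal itself.

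Gene names came from the platform annotation, which lists 34958 probe sets with 1 gene and 932 with several; 9160 others have no gene there. No gene was named from a probe set with several. Matching of Entrez identifiers to a RefSeq gene table succeeded for 34754 and changed 0 symbols. No genome coordinates were used here.

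Before the data were examined, the groups, most tests and alternatives, 31 gene lists and the rule for named genes were fixed. List tests were planned for all pairs and for the alpha4-low pairs, not for the difference between subclasses. Tests and alternatives chosen later are named as such below. The rule took, for all pairs, the 12 genes in each direction with the largest changes past the threshold, filled by the smallest p with the same sign in every pair. For the alpha4-low pairs it took 10, and for the difference between subclasses 8. It added up to 4 members of each list with the largest change, the genes used for sorting and every Itga4 probe set. Gene lists were tested on the brightest tested probe set per gene with camera (preset correlation 0.01, and again with an estimated correlation), with adjustment over the lists of at least 5 measured genes. The fry test of limma was also run on the lists.

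The models were tested on simulated data built from 22518 probe sets, with 200 of them changed by known amounts. For the all-pairs comparison, 5.97% of the probe sets changed by 1 log2 unit, 70.1% of those changed by 2 and 95.5% of those changed by 4 were recovered, with 7 false calls. The simulated noise came from the model with separate subclass coefficients and held no difference between subclasses. These all-pairs shares can therefore be too high for the real data. For the alpha4-low comparison the shares were 4.48%, 61.2% and 97.0%, with 3 false calls. For the difference between subclasses they were 0%, 0% and 22.7%, with 1 false call. Figures were drawn with matplotlib.

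Alternatives covered the pseudocount, the filter, the scaling, the variance prior, the threshold, sort purity as a covariate, the replicate block and the omission of each pair. Other splits of the arrays were also fitted, and each pair was taken as the lone one, among all 4 pairs and in sets of 3.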

Results

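Age-associated clonal expansions are populations of CD8 T cells that each descend from a single cell, carry the same T cell receptor and can come to fill much of the CD8 memory compartment of an old mouse. Gene expression was measured on 8 arrays, a clonal expansion and a polyclonal CD8 memory sample from each of 4 female mice. Mice 1 and 2 were 20 months old and mice 3 and 4 were 23 months old. Mice 1 to 3 were C57BL/10SnJ and mouse 4 was B10.BR. Cells were sorted from spleen and lymph nodes by surface CD8 and CD122 (the interleukin-2 receptor beta chain, high on memory CD8 cells), without MHC class II. Expansions carried a given T cell receptor V beta chain, and their polyclonal partners from the same animal lacked it. Sort purity was 91, 95, 96 and 98% for expansions 1 to 4 and 97, 75, 66 and 97% for the polyclonal samples. The labels put expansion 1 in an integrin alpha4-high subclass and expansions 2, 3 and 4 in an alpha4-low subclass. Their numbering is not uniform, since the description of expansion 1 counts the alpha4-low samples as 2, 4 and 5, and those of expansions 3 and 4 call them 4 and 5; each sample's own description gives its subclass. Median signal was between 46.5 and 75.1 per array, and 22050 to 30498 probe sets lay above the level of unspiked bacterial control probe sets. The number of arrays limits the precision.

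The first comparison asked how expansions differ from polyclonal memory cells of the same mouse, over all 4 pairs. Dsg2, which encodes the cell adhesion protein desmoglein 2, had the smallest p. Its signal was lower in 4 of 4 expansions, with a mean log2 difference of -2.48 ± 0.13 (SD, n = 4) and a mean signal of 142 against 824 (limma adjusted p = 0.126). A further Dsg2 probe set was lower in every pair (limma adjusted p = 0.163) and a dimmer one in 2 of 4 (limma adjusted p = 0.9998). Klra8 and Klra7, which encode inhibitory or activating receptors of the Ly49 family best known from NK cells, were also lower in every pair, by log2 differences of -3.68 and -2.93 (limma adjusted p = 0.147 for each). Slc35f3, a solute carrier gene, was higher in every pair at 3.24 (limma adjusted p = 0.147), and Rpl39l, a copy of a ribosomal protein gene, was lower in every pair at -3.11 (limma adjusted p = 0.147). Dsg2 was just under background in expansion 1, Klra7 was under it in expansions 1 and 3, and Rpl39l in expansions 1 to 3. Slc35f3 was under background in polyclonal samples 1 and 2, so the sizes of these genes are not exact. No probe set passed an adjusted p of 0.05 in limma. Of 22518 probe sets tested, 731 had an unadjusted p under 0.05 (214 higher, 517 lower), where 1126 would be expected by chance. After Slc35f3 the upward genes with the smallest p were Rad51ap1 (1.59), Kntc1 (1.31), Cdca2 (1.88), Asb6 (1.61), Dyrk1b (2.08), Pdlim1 (1.89), Ctc1 (1.53), Dscc1 (1.43), Cdc6 (1.28), Tfap4 (1.27) and Bub1 (1.15). None of them passed. Cdca2, Asb6, Dyrk1b, Pdlim1, Ctc1 and Tfap4 were under background in some polyclonal samples, so their sizes are not exact. Dyrk1b differed by only 0.01 in pair 3. Other tested probe sets of Cdca2, Asb6, Pdlim1, Ctc1 and Dscc1 were not higher in every pair, that of Pdlim1 being the brighter of its 2. Downward, after the 4 genes above, came Fat1 (-2.79), Crlf3 (-1.80), Lratd1 (-2.77), Macrod2 (-1.86), Rnf149 (-1.54), Kif1b (-1.46), Fsd2 (-2.25) and Iigp1 (-1.87). None of these passed (limma adjusted p from 0.543 to 0.9998), each had a smaller p than Rad51ap1, and some other tested probe sets of Kif1b were not lower in every pair. Fat1, Crlf3, Lratd1, Macrod2 and Fsd2 were under background in at least 1 expansion, so their sizes are not exact.

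Among the genes fixed in lists beforehand, cell cycle genes tended to higher values in expansions. Of 33 measured members 29 had a positive mean difference, with a median of 0.54, although 0 passed over all probe sets and 0 when adjusted over the list alone. The set ranked above other genes in camera with a preset correlation (adjusted p = 1.55e-10), but not otherwise (adjusted p = 0.510 with an estimated correlation). Cdc6, which licenses replication origins, had a log2 difference of 1.28 and the spindle checkpoint kinase gene Bub1 one of 1.15, each higher in 4 of 4 pairs (limma adjusted p = 0.9998 for both). The list's median difference was 0.68, 0.47, 0.99 and -0.36 in pairs 1 to 4, and its overall median was 0.28 without pair 3.

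NK receptor genes lay lower in expansions. Of 14 measured members 11 had a negative mean difference, with a median of -1.04; 0 passed over all probe sets and 3 adjusted over the list alone, all lower (Klra8, Klra7 and Klrc1). Camera gave an adjusted p of 1.87e-06 (adjusted p = 0.510 with an estimated correlation). The median was -0.57 without pair 3 and -0.58 without pair 4. Inhibitory receptor and exhaustion genes had 17 of 18 members lower, a median of -0.48, no member past either threshold (0 over all probe sets, 0 adjusted over the list alone), and a camera adjusted p of 0.00138 (adjusted p = 0.510 with an estimated correlation). That median was 0.53 in pair 1 and -0.49, -1.52 and -0.28 in pairs 2 to 4, and the list's camera call was lost without pair 3 (adjusted p = 0.150).

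The second comparison concerned the alpha4-low expansions against their own polyclonal cells, in 3 pairs. Itga4, the gene of the integrin subunit used to name the subclasses, checks the labels and is no independent finding. Its brightest probe set fell by 3.87 on the log2 scale (SE 0.41, limma adjusted p = 0.00958), from a mean signal of 4152 ± 3568 to 250.5 ± 164 (SD, n = 3 each). In pair 1 it read 11824 in the expansion and 3182 in the polyclonal cells. A further probe set fell by 3.94 (SE 0.51, limma adjusted p = 0.0193). The dimmest of the 3 tested did not pass, with a log2 difference of -1.45 (limma adjusted p = 0.926) and a value of 0.32 in pair 4.

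Apart from Itga4, the named genes that changed in the alpha4-low expansions were mostly lower. Gzmk, which encodes granzyme K of cytotoxic granules, fell by 4.57 (SE 0.51, limma adjusted p = 0.00958), from a mean signal of 5622 ± 5161 to 182 ± 64.8 (SD, n = 3 each). Ikzf2, the gene of the transcription factor Helios, fell by 3.72 (SE 0.49, limma adjusted p = 0.0193), while its other tested probe set missed the threshold (-3.26, limma adjusted p = 0.0528). Nr4a2, an orphan nuclear receptor gene induced by antigen receptor stimulation, fell by 3.85 (SE 0.56, limma adjusted p = 0.0309). The size of this fall is not exact, since expansion 3 read 25.7, under background. For Nr4a2 there were also less bright probe sets. These 2 other tested probe sets did not pass, at -2.66 and -1.05 (limma adjusted p = 0.121 and 0.966). Casp1, the inflammasome protease gene, fell by 3.60 (SE 0.55, limma adjusted p = 0.0410). The probe sets that passed for Coch and Ryr3, encoding the secreted protein cochlin and an intracellular calcium channel, were not above background in any alpha4-low expansion. Their signals were at least 8.42-fold and at least 4.44-fold lower there (limma adjusted p = 0.0271 and 0.0309). Over the alternative settings in which each was fitted, the call held in 10 of 14 for Coch and in 7 of 14 for Ryr3. Another tested Ryr3 probe set did not pass (-0.37, limma adjusted p = 0.996) and was higher in expansion 4. Slc35f3 rose by 3.66 (SE 0.48, limma adjusted p = 0.0193), from 43.98 ± 7.69, close to background, to 656 ± 282 (SD, n = 3 each). In total 12 of 22518 probe sets passed, 1 higher and 11 lower, and 9 of them carried a single gene name, of 8 distinct genes. All differences have the same sign in 3 of 3 pairs. In pair 1, 9 of the 12 lay in the opposite direction and 3 in the same direction.

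**Figure D1:**
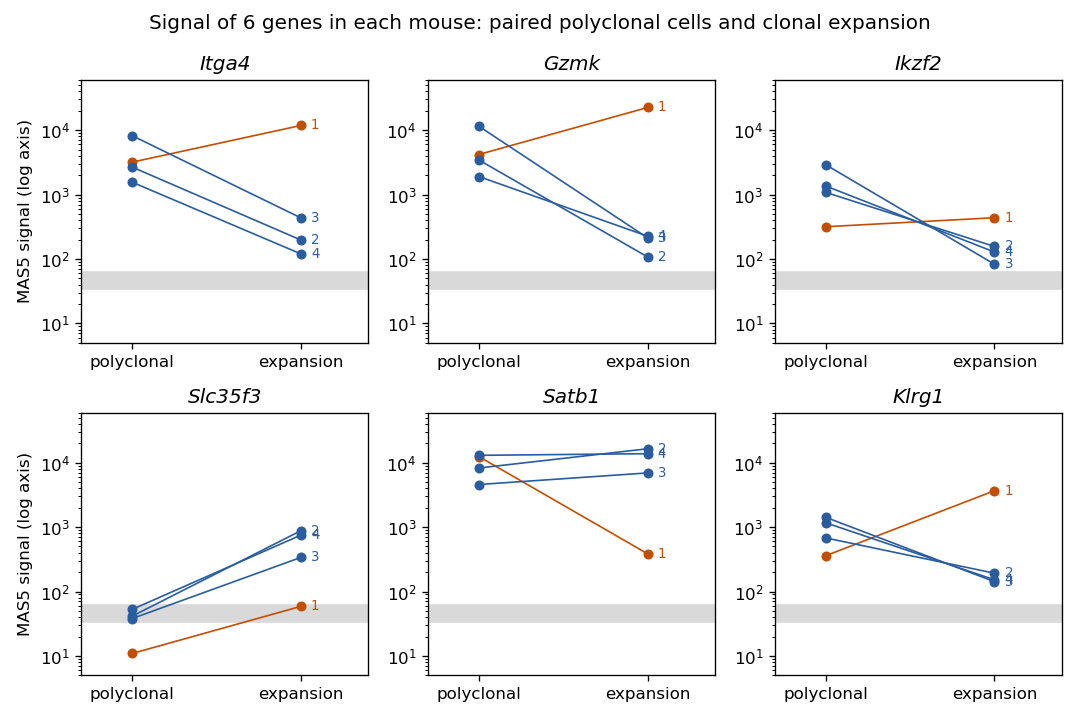
Array signal of 6 genes on a log axis, in polyclonal cells and the clonal expansion of each mouse joined by a line; the number is the mouse, orange is the alpha4-high pair, blue the 3 alpha4-low pairs, and the grey band spans the background levels of the arrays (33.7 to 61.9). Itga4, Gzmk and Ikzf2 are lower in expansions 2, 3 and 4, while Satb1 reads 384 in expansion 1 against 12442 in its partner.

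Genes that narrowly missed the threshold included Klra8 (log2 difference -3.90, limma adjusted p = 0.0528), the transcription factor gene Maf (-2.83, limma adjusted p = 0.0547) and Dsg2 (-2.45, limma adjusted p = 0.0587). This Maf probe set was under background in expansions 2 and 4, so its size is not exact. The other tested Maf probe sets, all brighter, had differences of -3.125, -2.715 and -2.721 (limma adjusted p = 0.0637, 0.263 and 0.381). Upward, the genes with the smallest p after Slc35f3 were Hps4 (1.81), Ube2e2 (2.05), the replication factors Dtl (1.81) and Rad51ap1 (1.83), Myh10 (1.62), Dscc1 (1.76), the checkpoint kinase Chek1 (1.55), Lasp1 (1.22) and Me2 (1.69). None of these 9 passed, with limma adjusted p from 0.468 to 0.663, and among other tested probe sets of Dtl, Dscc1, Lasp1 and Me2 were some not higher in every alpha4-low pair.

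Inhibitory receptor and exhaustion genes stood lower in the alpha4-low expansions. Of 18 measured members 15 were lower, with a median of -1.03; 1 passed over all probe sets (Nr4a2) and 7 adjusted over the list alone, all lower. The checkpoint receptor genes Ctla4 and Pdcd1 had log2 differences of -4.08 and -3.75 (limma adjusted p = 0.0754 and 0.0696), though Ctla4 was above background in only 2 and Pdcd1 in only 1 of the 3 alpha4-low expansions, so their size is uncertain. Tox2, a transcription factor gene, had a difference of -2.72 (limma adjusted p = 0.0860). Camera placed the set below other genes (adjusted p = 3.71e-08; adjusted p = 0.525 with an estimated correlation), with a median of -0.55 when pair 3 was left out. NK receptor genes had 11 of 14 members lower and a median of -1.31, with 0 past over all probe sets and 7 adjusted over the list alone. Besides Klra8 the leading members were Klra7 (-2.67), Klrg1, a receptor of terminally differentiated effector cells (-2.66), and Klre1 (-2.47). Camera gave 2.65e-08 after adjustment for this set (adjusted p = 0.525 with an estimated correlation). The NK cell marker list, which shares 4 of its members with it, among them Klra8 and Klre1, had 5 of 6 members lower, 0 past over all probe sets and 3 adjusted over the list alone. Its camera adjusted p was 3.26e-04 (adjusted p = 0.525 with an estimated correlation), and its median moved from -1.31 to 0.09 without pair 3.

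Cytotoxic effector genes had 16 of 18 members lower with a median of -0.26; Gzmk alone passed, both over all probe sets (1) and adjusted over the list alone (1). Ifng (-1.41), Ccl3 (-1.07) and Prf1, the perforin gene (-0.91), did not pass. The camera adjusted p was 0.0141 (adjusted p = 0.646 with an estimated correlation). Cell cycle genes had 26 of 33 members higher and a median of 0.55, with 0 past over all probe sets and 0 adjusted over the list alone (camera adjusted p = 6.16e-07; adjusted p = 0.646 with an estimated correlation). Without pair 3 that median was 0.00, the call remaining (adjusted p = 0.0181). Genes reported for aged CD8 T cells had a median of -0.23 (-0.41 without pair 4) and a camera adjusted p of 0.0375 (adjusted p = 0.646 with an estimated correlation), with Gzmk past over all probe sets (1) and Gzmk and Pdcd1 adjusted over the list alone (2). T cell receptor signalling genes had a median of -0.33, with 0 past over all probe sets and 0 adjusted over the list alone, and a camera adjusted p of 0.0457 (adjusted p = 0.646 with an estimated correlation) that was lost without pair 2 or pair 4.

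**Figure D2:**
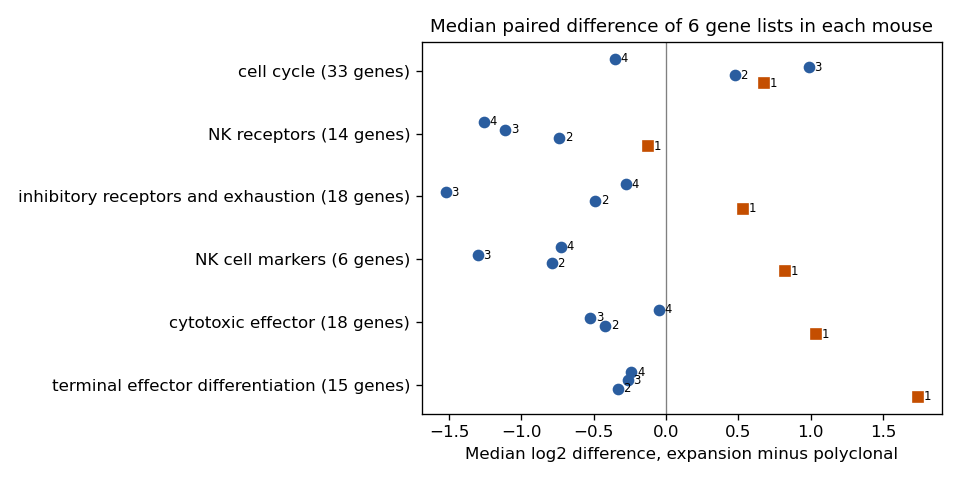
Median log2 difference, expansion minus polyclonal, over the measured genes of 6 lists in each mouse; orange squares are the alpha4-high pair and blue circles the alpha4-low pairs, numbered by mouse. The terminal effector median is 1.74 in pair 1 and -0.33, -0.27 and -0.24 in pairs 2 to 4.

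These alpha4-low calls depend on the pairing and on the variance model, since 0 probe sets passed in limma without mouse as a block or without an intensity trend, with 621 and 1097 at an unadjusted p under 0.05. With sort purity as a covariate 14 passed, 3 of them among the 12, and the Itga4 probe set no longer did (log2 difference -3.56, limma adjusted p = 0.0576).

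The third comparison tested whether the paired difference itself differs between the alpha4-low expansions and the alpha4-high expansion. Satb1, which encodes a chromatin organiser of T cells, read 384 in expansion 1 against 12442 in its partner, but 12371 ± 4899 against 8605 ± 4215 in the alpha4-low pairs (SD, n = 3). The difference of differences was 5.56 (SE 0.74, limma adjusted p = 0.0472), and a further Satb1 probe set gave 4.63. The 3 other tested Satb1 probe sets did not pass, at 5.10, 3.02 and 1.58 (limma adjusted p = 0.0624, 0.437 and 0.977). Bmpr1a, a bone morphogenetic protein receptor gene, showed 6.01 (SE 0.92), with 61.1 against 3104 in pair 1; its 4 other tested probe sets did not pass, at 4.84, 4.58, 3.82 and 0.24. The probe sets that passed for Tanc1 and Lypd6b were not above background in expansion 1, where they were at least 22.12-fold and at least 23.1-fold lower than in the partner. A dimmer Tanc1 probe set did not pass (0.53, limma adjusted p = 0.9997). In the other direction, higher in expansion 1 and lower in the alpha4-low expansions, stood Gzmk (-6.99), Klrg1 (-5.99) and Itga4 (-5.76), together with Tmem255a and Coch. Neither of these last was above background in any alpha4-low expansion. They were 38.8-fold and 11.8-fold higher in expansion 1 than in its partner, and at least 3.29-fold and at least 8.42-fold lower in the alpha4-low expansions. Gzmk read 22479 in expansion 1 against 4187 in its partner, and Klrg1 3668 against 359. In all, 12 probe sets passed, 7 with a positive and 5 with a negative difference, each at a limma adjusted p of 0.0472, and 3 of them were also among the 12 of the alpha4-low comparison.

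Further genes missed the threshold closely. Dmrta1 had a difference of 5.00 (limma adjusted p = 0.0507). S100a4 (-6.08), the inflammasome cytokine gene Il18 (-5.50), Atp1b1 (-7.33), Sh3bp5 (4.36), Ccdc102a and the kinase gene Yes1 all had a limma adjusted p of 0.0624. Ccdc102a and Yes1 read 2.33 and 44.87 in expansion 1, under the background of 46.6 there, so their differences have no exact size. No other tested probe set of these 7 genes passed.

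Lists were also tested for the difference between subclasses, which had not been planned. Terminal effector and cytotoxic effector genes had the smallest adjusted p in camera, the same for both. Of the 15 terminal effector members 13 had a negative difference, with a median of -2.31 (-1.53 without pair 3); Klrg1 alone passed over all probe sets (1) and 7 adjusted over the list alone. Zeb2, an effector transcription factor gene, and Anxa2 had differences of -3.58 and -2.84, and the chemokine receptor gene Cx3cr1 one of -3.11, none past over all probe sets. Zeb2 was above background in only 2 polyclonal samples and not in that of pair 1, so its size is uncertain. Camera gave an adjusted p of 4.85e-06 (adjusted p = 0.518 with an estimated correlation). Cytotoxic effector genes had 17 of 18 members negative and a median of -1.51, with 1 member past over all probe sets (Gzmk) and 1 adjusted over the list alone; Gzma (-4.55), Ccl3 (-2.56) and Gzmb (-2.42) did not pass. Their camera adjusted p was 4.85e-06 (adjusted p = 0.518 with an estimated correlation). Inhibitory receptor and exhaustion genes had 13 of 18 negative and a median of -1.51 (-0.98 without pair 3). None passed over all probe sets (0) and 8 did adjusted over the list alone, 7 of them negative, among them Ctla4 (-6.25), Batf (-5.91) and Pdcd1 (-5.66), the last 2 above background in 1 of the 3 alpha4-low expansions. Their camera adjusted p was 1.39e-04 (adjusted p = 0.518 with an estimated correlation).

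Smaller lists differed the same way. NK cell markers had all 6 members negative and a median of -1.70, with 0 past over all probe sets and 2 adjusted over the list alone, Klre1 and Gzma (camera adjusted p = 0.00647; adjusted p = 0.518 with an estimated correlation). Genes reported for aged CD8 T cells had a median of -0.70, with Gzmk past over all probe sets (1) and Gzmk and Pdcd1 adjusted over the list alone (2) (camera adjusted p = 0.00710; adjusted p = 0.518 with an estimated correlation). CD4 and regulatory T cell genes had 8 of 10 members negative and a median of -1.05, with 0 past over all probe sets and 2 adjusted over the list alone (camera adjusted p = 0.0277; adjusted p = 0.518 with an estimated correlation). The sorting markers, which hold Itga4 as their only member past over all probe sets (1) or adjusted over the list alone (1), had a camera adjusted p of 0.0403 (adjusted p = 0.598 with an estimated correlation).

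The alpha4-high subclass is a single pair, assumed in limma to vary like the others, and 1 other single pair could also stand apart. In limma fits to 3 pairs, pair 3 against pairs 2 and 4 gave more calls than the lowest count with pair 1 as the lone one. Against the same pairs, however, pair 1 gave more calls than the alpha4-low pair in every set. Pairs 2 and 4 as the lone one gave far fewer. With sort purity as a covariate 14 passed, 4 of them among the 12, and 0 probe sets passed without a pseudocount, after quantile normalization or without the trend, with 1562, 1550 and 1572 at an unadjusted p under 0.05.

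The genes used to sort the cells were looked at next. The brightest Cd8a probe set read 19585 on average in expansions and 18920 in polyclonal cells, while another read 5563 and 9264 (log2 difference -0.68, limma adjusted p = 0.9998). The tested Il2rb probe set read 334 and 285. Cd74, the MHC class II invariant chain gene, had a log2 difference of 1.399 over the 4 pairs (limma adjusted p = 0.9998), at mean signals of 156 and 78.8, and H2-Eb1 read 79.2 and 59.3. The brightest MHC class II probe sets, both of H2-Aa, read 930.6 and 819.7, and 477.8 and 418.6, although the cells were sorted to lack the protein. Other H2-Aa probe sets, too dim to be tested, had mean signals of 42.1 and 37.7 over all arrays. The probe sets of this gene therefore do not settle whether its transcript was present. Of the listed T cell receptor segments, only Trbv1 and Trbv13-2 had a tested probe set that carried their name alone. Trbv13-2, of the V beta family used in the sort of mouse 2, read 67.3 in expansion 2 against 119 in the polyclonal cells that were sorted to lack it, so this dim probe set did not show the sort. Whether it measures that segment, and whether the labels of pair 2 hold, was not tested; an exchange would turn every difference of that pair. In this pair Itga4 read 197 in the sample labelled as the alpha4-low expansion and 2676 in its partner.

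Markers of other cell types were measured in the same samples. Neutrophil genes had 6 of 7 members higher over the 4 pairs with a median of 0.46, and 0 past over all probe sets and 0 adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.510 with an estimated correlation). S100a8 and S100a9 had log2 differences of 1.03 and 0.97, neither past. That median was 1.17, 1.96, -0.45 and 0.36 in pairs 1 to 4, and its call was lost without pair 1 or pair 2 (adjusted p = 0.137 and 0.536). Without pair 3 the median of the list was 0.94 (adjusted p = 2.71e-06). Monocyte and macrophage genes had 11 of 13 members higher with a median of 0.19, 0 past over all probe sets and 0 adjusted over the list alone (camera adjusted p = 0.0369; adjusted p = 0.510 with an estimated correlation). This call was lost without the same pairs (adjusted p = 0.137 and 0.575), and the median was 0.69 without pair 3. Lyz1 (0.92) and Csf1r (0.998) led them with Slc40a1 and did not pass. NK cell markers were lower over the 4 pairs with a median of -0.62, 0 past over all probe sets and 1 adjusted over the list alone (camera adjusted p = 0.0404; adjusted p = 0.510 with an estimated correlation). This call was lost without pair 2, 3 or 4 (adjusted p = 0.169, 0.437 and 0.0591), and the median was -1.31 without pair 1, -0.33 without pair 4 and 0.06 without pair 3. Control probe sets for the ends of the beta-actin transcript gave 3'/5' signal ratios between 34.9 and 89.7, higher in the expansion in 2 of 4 pairs (exact paired permutation p = 0.75, two-sided). For Gapdh the ratio was higher in 1 of 4 (exact paired permutation p = 0.25).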

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

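The test of RNA length, the test of a lone pair in sets of 3 pairs, the count of splits at an unadjusted p and the background level were chosen after the result they bear on was seen. List tests of the difference between subclasses were not in the plan. The other tests were set before.

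The alpha4-high pair stood apart from the alpha4-low pairs: in the test of the difference itself, 12 probe sets passed, and the log2 differences of the named ones were -8.74 for Tmem255a, -7.82 for Coch, -6.99 for Gzmk, 6.01 for Bmpr1a, -5.99 for Klrg1, -5.76 for Itga4, 5.56 and 4.63 for Satb1, 5.42 for Tanc1 and 5.38 for Lypd6b. Those of Tmem255a, Coch, Tanc1 and Lypd6b rest on signals not above background in either the alpha4-low expansions or expansion 1, so these sizes are not exact and only lower bounds are measured. When each of the other pairs took the place of the lone one the highest count was 0, against 12 for pair 1. Pair 1 then adds to the residual, however. In sets of 3 pairs without pair 1, pair 3 against pairs 2 and 4 gave 167. This was more than the lowest count of 64 with pair 1 as the lone one. Pairs 2 and 4 as the lone one gave far fewer than 64. That a lone pair other than pair 1 can stand apart therefore remains open for pair 3, but was not seen for every pair. The spread of pair 1's differences was 0.782 times that of the most variable other pair, pair 2, but above that of pair 4 (0.701 against 0.650). Such a spread also holds real differences between the samples, so it cannot decide on noise in the arrays of pair 1. The alpha4-high subclass remains an open and biological explanation, as a hypothesis, but with a single such mouse it cannot be separated from anything else particular to that animal, and that was not tested.

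Falls outnumbered rises in the alpha4-low expansions, 11 against 1. The ratio of expansion to control beta-actin 3'/5' signal was 0.603 in pair 4 and above 1 in pairs 2 and 3 (at most 1.36), while the Gapdh 3'/5' ratio went the other way in each (6.56 against 5.66 in pair 4, 5.63 against 8.41 in pair 2 and 2.78 against 4.62 in pair 3). The controls point in opposite directions, so shorter RNA stays open. Other cells in the less pure polyclonal sorts of pairs 2 and 3 remain open, since the 122 probe sets that fell by at least 2 log2 units in both of those pairs had a median change of -0.30 in pair 4 (bootstrap interval -0.69 to -0.07), between the values set in advance for and against that explanation, and 61.5% of them were lower there against 49.7% of all probe sets. The bootstrap resampled these probe sets within pair 4, so its interval does not measure the spread between mice. The 11 called falls were also lower in pair 4, whose sorts were 98 and 97% pure, with log2 differences from -2.45 to -6.84. Some of these rest on signals under background in expansion 4. Pair 4 is a single mouse and helped to call them, so these values do not settle the question. Of the 10 splits of these 6 arrays, 1 gave as many probe sets as the real split (14 when fitted on these arrays alone), the highest other count being 1; the 3 others that also part every pair gave 0, and so few splits cannot give a share under 0.05.

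For the comparison over all 4 pairs, 32 splits of the 8 arrays could be fitted with the block, and all 32 gave at least the real count of 0, which any split must; the highest was 9. That count therefore tests nothing. At an unadjusted p under 0.05, 29 of the 32 splits gave at least the real count of 731, up to 2086. Of the 8 splits that part every pair, 7 gave as many at an unadjusted p, the real one included. The others of these 8 exchange the labels of some pairs and keep those of the rest. The split with 9 calls grouped the alpha4-high expansion with the polyclonal samples of the alpha4-low pairs, so it carried the difference between subclasses. Such splits can hold real differences and do not measure chance alone. Whether chance is the source of the 731 therefore cannot be decided from them.

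Samples far from the other 3 of their group were found in 20 of 174 groups of values, where chance gives about 8.70, and in 17 of the 20 it was expansion 1 or pair 1. The named genes include those chosen for differing in that pair, and the expansions pool both subclasses. In expansion 1 the signals that stood apart were 22479 for Gzmk, 17320 for S100a4, 10718 for Casp1, 8341 for Itga4, 3804 for Il18, 3668 for Klrg1, 2527 for Tmem255a, 773 for Sh3bp5, 274 for Kntc1, 21.2 for Lypd6b and 2.33 for Ccdc102a, the last 2 under background. The paired log2 differences of pair 1 that stood apart were -5.37 for Lypd6b, -5.13 for Tanc1, -5.00 for Satb1, -3.96 for Dmrta1, 1.89 for Itga4 and 1.33 for Maf. Elsewhere, Bub1 read 417.5 in expansion 4 and Dmrta1 1750.2 in polyclonal sample 2, and the median signal of expansion 3 was 75.1.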

How the results depend on the processing

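The alternatives with the pseudocount at the median, without the pairs of less pure sorts, and those of the list differences between subclasses were chosen after the data were seen. Over all 4 pairs the count stayed at 0 in every fitted alternative except 457 at an unadjusted p under 0.05 with at least a 2-fold change, and between 0 and 14 when pairs were left out, the 14 without pair 1. For the alpha4-low pairs, 12 became 37 at an adjusted p under 0.10, 979 at the unadjusted p with a 2-fold change, 22 with a filter at the upper quartile, 6 after quantile normalization, 29 with equal medians, and 0 both without an intensity trend in the prior variance and without the replicate block; leaving out pairs gave 14 to 157 (138 without pair 3 and 157 without pair 4, each with 1 residual degree of freedom). Itga4 passed no longer without the trend (-3.87, limma adjusted p = 0.0790), with sort purity beside the replicate block (-3.56) and without the replicate block (-3.86, limma adjusted p = 0.144); its limma adjusted p over all alternatives was between 2.4e-11 and 0.144. For the difference between subclasses, 12 became 0 without a pseudocount, after quantile normalization and without the trend, 25 with the pseudocount at the 25th percentile and with no filter, 55 with it at the median, 63 with the upper quartile filter, 56 with equal medians, 68 at an adjusted p under 0.10, and 1479 at the unadjusted p with a 2-fold change; leaving out alpha4-low pairs gave 64 to 277. The numbers of gene lists past camera's threshold, 6 for all pairs, 7 for the alpha4-low pairs and 7 for the difference, all became 0 with an estimated correlation. No list passed in fry either. Its lowest adjusted p was 0.532 for all pairs, 0.284 for the alpha4-low pairs and 0.300 for the difference. All probe sets of the listed genes gave 11 lists for all pairs, and no filter gave 11 for the alpha4-low pairs, where leaving out pairs gave 7 to 13. The ribosomal protein list reversed without pair 3, from a median of 0.14 (not past the threshold) to -0.042 (camera adjusted p = 0.0385), and was at 0.45 without pair 2. Another 82 values past no threshold in either setting changed direction, which for lists is that of camera and not of the median. By the sign of the median itself, 4 further values past the threshold in at least 1 setting turned: NK cell markers over all pairs to 0.06 without pair 3 and to 0.07 with no filter, and in the alpha4-low pairs to 0.09 without pair 3, and cytotoxic effector genes over all pairs from 0.13 to -0.26 without pair 1; the cause was not tested in any of these cases. Equal medians moved the median of all probe sets from -0.07 to 0.10 in the alpha4-low comparison and from -0.10 to 0.18 in the difference between subclasses, where quantile normalization moved it to 0.05. The fit without the replicate block left the count over all pairs at 0; the difference between subclasses was not fitted without it. A model with the scan record as a batch was not run, since a single array carries its own record. Leaving out both less pure pairs from the alpha4-low comparison leaves no residual degrees of freedom. Signals below 61.9 cannot be told from background on the noisiest array.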

Other observations

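Several other gene groups did not pass, which does not show that they were unchanged. In the alpha4-low pairs, type I interferon response genes had a median log2 difference of -0.08 over 25 measured members, oxidative phosphorylation genes 0.15 over 46, glycolysis genes 0.22 over 15 and ribosomal protein genes 0.14 over 32, none past camera's threshold, with 0 members of any of the 4 lists past over all probe sets and 0 adjusted over the list alone. Chemokine receptor and trafficking genes (14 measured) and T cell identity genes (13 measured) had medians of -0.53 and -0.45, larger than that of some lists that passed, at camera adjusted p of 0.176 and 0.139, with 0 members of either past over all probe sets and 0 adjusted over the list alone. Iigp1, an interferon-inducible GTPase gene, nevertheless had a signal of 198 ± 73.3 in alpha4-low expansions against 1229 ± 846 in their partners (SD, n = 3 each), a log2 difference of -2.46 that did not pass (limma adjusted p = 0.0634; another probe set -1.997, limma adjusted p = 0.311), while expansion 1 read 1025 against 1103.

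Ly49 family probe sets read lower in expansions, though none passed over all probe sets. All 5 tested probe sets listed with Klra genes were lower on average over the 4 pairs, 4 of them in every pair, with a median log2 difference of -2.93; Klra17 was at 0.13 in pair 1. Klra8 read 9501 on average in polyclonal cells, mostly from mice 2 and 4 (15079 and 21818, against 441.5 and 665 in mice 1 and 3), and 410.5 in expansions, and Klra5 198 and 48.1. Several of these probe sets share sequence with related Klra genes and cannot be assigned to a single gene. Polyclonal populations hold many clones, of which some may express a given Ly49 receptor, so an expansion of a clone without it is a biological hypothesis that was not tested. A candidate source is NK cells in the polyclonal sorts, although those were gated on CD8. In a test set in advance, Ncr1, Klrb1c, Fcer1g and Tyrobp were to fall by more than 1 log2 unit if so. Their median change over the 4 pairs was -1.10, but this is the value of Ncr1 itself, which was not above background in any polyclonal sample, so the test does not speak for or against NK cells and the source stays open. Klrb1c had no probe set named here, and the others were Tyrobp at -1.15 ± 1.79 and Fcer1g at 0.71 ± 1.02, beside Ncr1 at -1.10 ± 1.45 (SD, n = 4 pairs). Mean polyclonal signals were 119 for Tyrobp, 24.3 for Ncr1 and 56.3 for Fcer1g.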
